A study of Saccharomyces cerevisiae with 25 samples.

How the data were processed

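Transcript levels were measured in budding yeast (Saccharomyces cerevisiae) with Affymetrix arrays carrying 9275 probe sets, 1 array per sample. Per the labels, total RNA was extracted with acid phenol, labelled with biotin and hybridised by the standard Affymetrix procedure. Cells grew in glucose-rich medium and were collected in exponential phase, or 30 min after the glucose had run out. The labels state that every sample was made 2 times independently, so p-values measure the spread between such preparations. They also state that the authors discarded 3 problematic arrays (1 each of caf1 after depletion, not4 in exponential phase and not5 in exponential phase), and that no not5 sample was made after depletion because the strain flocculates there.

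The authors deposited 1 table of log2 values, 1 column per array and 1 line per probe set. The software, background correction and normalization behind it are not given in the sources used here. The log base is not stated either and was inferred from the values, which run from 1.36 to 13.94 with 0 missing. No centring per gene was seen, and direction is not in question since each array holds 1 sample. The medians of the exponential arrays were 5.28 and 5.28 (caf1), 5.33 and 5.32 (caf130-labelled), 5.28 and 5.20 (ccr4), 5.37 and 5.36 (not2), 5.22 and 5.24 (not3), 5.29 (not4), 5.33 (not5) and 5.27 and 5.20 (wild-type). Those of the depletion arrays were 5.25 (caf1), 5.31 and 5.26 (caf130-labelled), 5.26 and 5.23 (ccr4), 5.29 and 5.29 (not2), 5.23 and 5.27 (not4) and 5.28 and 5.26 (wild-type). The values were therefore used as deposited, with no further normalization and no pseudocount. If the base were another, every fold change would scale by 1 factor and the tests would stay as they are.

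Probe sets were named through the platform annotation given with the series, with symbols updated by Entrez number to the R64 reference, where all 5656 tested genes were found. Of the probe sets, 6504 carried 1 gene symbol, 328 several and 2443 none, and only the first kind was used. For the 315 genes with several probe sets, the set with the highest mean over the 25 arrays was taken. Among the genes tested, 295 lie on probe sets whose name ending marks a shared or otherwise less specific set, and they were kept. Of these, 94 lie on sets ending in _s_at or _x_at. Of 137 cytosolic ribosomal protein genes, 80 were measured.

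Groups were taken from the sample titles (strain and growth condition), giving 14 groups, 11 of 2 arrays and 3 of 1. One linear model of group means was fitted to all 25 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend; 11 residual and 9.03 prior degrees of freedom). The groups of 1 array borrow their spread from the others. Comparisons were each deletion strain against wild type within a condition, depletion against exponential phase within a strain, the difference of that response from the wild-type response, and the mean of not2, not3, not4 and not5 against the mean of caf1 and ccr4 in exponential phase. P-values were adjusted by Benjamini-Hochberg within each comparison and called at 0.05. The number of arrays limits the precision. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

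The comparisons, the alternatives and 27 gene lists were fixed before the data were examined. The lists were CCR4-NOT subunits, mRNA decay factors, cytosolic ribosomal proteins, ribosome biogenesis, mitochondrial ribosomal proteins, general stress response, trehalose and glycogen metabolism, glucose-repressed carbon use, fatty acid beta-oxidation, respiratory chain and ATP synthase, TCA cycle, glycolysis and fermentation, hexose transporters, heat shock chaperones, proteasome, amino acid biosynthesis, pheromone response, G1/S cell cycle, daughter-cell separation, histones, cell wall integrity, flocculation and adhesion, DNA damage response, iron regulon, a-specific genes, alpha-specific genes and auxotrophic marker genes. Of their 782 members, 709 were measured. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Of 196 list calls, 26 held with the estimated correlation and 170 did not.

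Genes were named by a rule fixed beforehand: (a) the 9 subunit genes, the deleted one first; (b) the 5 highest and 5 lowest called genes whose arrays do not overlap between the sides, leaving out the deleted gene (no overlap condition for a difference of responses); (c) in a list with at least 3 called members, up to 4 with the greatest change; (d) mating-type and auxotrophic marker genes; and (e) FLO genes in not5. The rule gave 1456 calls of named genes, of which 533 (36.6%) were lost on leaving out 1 array, 557 under any setting, and 899 were kept. The text takes genes in the order of the rule and, apart from genes whose lost calls it states, skips those whose call was lost, a choice made after the data were seen.

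Alternatives were quantile normalization, leaving out the dimmest 25% of genes (4242 left), a minimum change of 2-fold and the replicate number as a block. Further ones were eBayes without trend, each array left out in turn, and the spread taken from fewer arrays. For comparisons within a condition these were all arrays of that condition, and for a response the arrays of that strain. Added after the data were seen were the removal of a trend on coding length (lowess, span 0.3, over 5486 genes with a length), the NOT side without not2 or without not4, and a fit without the not4 exponential and caf1 depletion arrays. The trend removed included each array's level, so that setting also recentred the arrays. A count or split that moved under it is therefore not by itself evidence of a length effect. Correlations between strains that share wild-type arrays were set beside 20 simulations of unchanged groups.

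The test was checked on simulated data with 200 of 5656 genes changed. For ccr4 in exponential phase 30% of 2-fold and 91% of 4-fold changes were recovered, with 4% false calls. For not4 in exponential phase these were 18%, 76% and 6.9%, for wild-type depletion 33%, 87% and 4.8%, and for the ccr4 difference of responses 6%, 59% and 7.1%. All recovered changes had the right sign (100%). With the proteasome list raised by 0.5 in a simulated ccr4 comparison, camera called it (adjusted p = 5.46e-12) and 0 of the 26 other lists. The simulated genes were independent of each other and had the same spread in every group. The false-call rates and the list check therefore do not cover correlated genes or groups of unequal spread.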

Results

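Gene expression was measured on 25 Affymetrix arrays of total RNA from budding yeast. The arrays covered a wild-type strain and 7 strains labelled as each lacking 1 subunit of the Ccr4-Not complex, a conserved complex that shortens the poly(A) tails of mRNAs and also acts on transcription. Ccr4 and Caf1 (gene POP2) are its deadenylases, Not4 (gene MOT2) is a ubiquitin ligase, and Not2 (gene CDC36), Not3, Not5 and Caf130 are further subunits. All 8 strains were collected in exponential phase in glucose-rich medium (14 arrays), and the wild type and the caf1, caf130, ccr4, not2 and not4 strains were also collected 30 min after glucose had run out (11 arrays). Of the 14 groups, 11 had 2 arrays. The not4 and not5 exponential groups and the caf1 depletion group had 1 array each, so they had no replicates and were assumed to vary like the other groups. The array medians lay between 5.20 and 5.37 on the log2 scale, and 5656 genes were tested. Values below are log2 fold changes ± SE from limma, with n = 2 arrays per group except in those 3 groups, and p-values are Benjamini-Hochberg adjusted within a comparison unless another adjustment is named.

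The transcript of each deleted gene was examined first, in all 25 arrays. POP2 lay between 2.39 and 3.02 in the 3 caf1 arrays and between 7.61 and 7.81 in the 4 wild-type arrays, and CDC36 lay between 3.01 and 3.81 in the 4 not2 arrays and between 8.02 and 8.42 in wild type. CCR4 read 5.03 and 4.67 in the exponential ccr4 arrays and 3.81 and 3.56 after depletion, against 7.96 to 8.32 in wild type. NOT3 read 2.31 and 2.25 in the not3 arrays, MOT2 read 2.48, 3.05 and 2.51 in the not4 arrays, and NOT5 read 3.90 in the not5 array. These POP2, NOT3 and MOT2 readings and the lowest CDC36 reading lay below the lower quartile of their own arrays. The CCR4 reading of 3.56 and the NOT5 reading of 3.90 lay close to it. Background may limit the size of a fall there. Against wild type in exponential phase the changes were -5.02 ± 0.26 for POP2 (adjusted p = 1.44e-10), -4.82 ± 0.32 for CDC36 (adjusted p = 4.05e-09), -3.29 ± 0.45 for CCR4 (adjusted p = 0.00011), -2.89 ± 0.34 for NOT3 (adjusted p = 8.1e-05), -2.72 ± 0.38 for NOT5 (adjusted p = 0.000263) and -2.14 ± 0.37 for MOT2 (adjusted p = 0.00187). CAF130 went against its label: it read 5.92 and 6.60 in the exponential arrays labelled caf130 and 5.61 and 5.30 in wild type (0.81 ± 0.29, adjusted p = 0.218), and after depletion it averaged 5.72 on both sides (adjusted p = 1). Whether the CAF130 probe set lies in the deleted part was not analysed here, and these 4 arrays are called arrays labelled caf130 throughout.

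TRP1, a tryptophan biosynthesis gene used as a marker in strain construction, separated the strains as well. It read 7.90, 7.88 and 8.88 in the caf1 arrays, 7.43, 6.73, 7.83 and 7.94 in the ccr4 arrays, and 7.27 and 7.69 in the depletion arrays labelled caf130. The 2 exponential arrays labelled caf130 read 3.59 and 5.52, below all of those, so whether the arrays labelled caf130 come from the same strain in both conditions stays in doubt, and this limits each comparison between their conditions. The wild-type, not2, not3, not4 and not5 arrays read between 2.09 and 3.14. The caf1 and ccr4 strains thus differed from wild type in this marker as well as in the deletion, which limits each of their comparisons with it. The rise of TRP1 in the exponential arrays labelled caf130 (1.79 ± 0.41, adjusted p = 0.0483) was not called without replicate 2 of that group (adjusted p = 0.472), or without wild-type exponential replicate 1 (adjusted p = 0.17) or 2 (adjusted p = 0.369). It was not called under 3 other settings either. Its adjusted p was 0.0636 with a replicate block, 0.109 with the length trend removed and 0.0691 with the spread of the exponential arrays only.

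**Figure D1:**
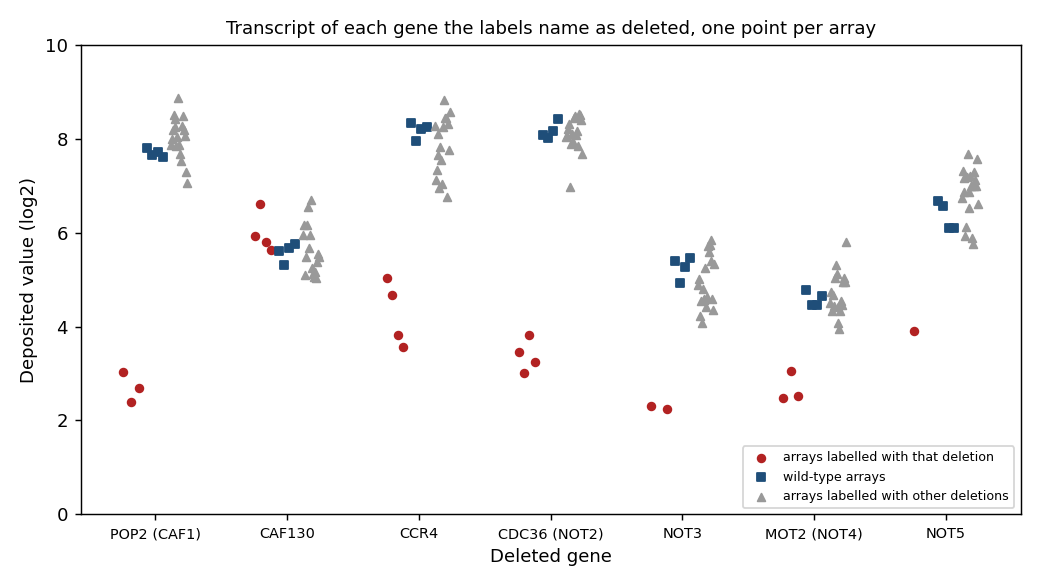
Deposited log2 value (vertical axis) of the transcript of each gene that the labels name as deleted (horizontal axis), 1 point per array, for the arrays labelled with that deletion (circles), the wild-type arrays (squares) and the arrays labelled with other deletions (triangles). For 6 of the 7 genes the circles lie below every other point, and for CAF130 the 4 circles, between 5.64 and 6.60, lie among the others.

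Glucose depletion of the wild type, the reference for the mutants, lowered the translation machinery and raised stress and respiratory genes. Of 80 measured cytosolic ribosomal protein genes, 74 fell (78 adjusted over the list alone), with a median of -2.01 (camera adjusted p = 4.5e-30, and adjusted p = 0.0752 with an estimated correlation). Examples are RPL7B at -4.01 ± 0.35 (adjusted p = 5.8e-08) and RPS9B at -3.93 ± 0.29 (adjusted p = 8.88e-09). Of 79 ribosome biogenesis genes, 72 fell (75 adjusted over the list alone; median -1.82, camera adjusted p = 5.5e-22, and adjusted p = 0.142 with an estimated correlation), among them the nucleolar protein gene NSR1 at -3.44 ± 0.45 (adjusted p = 5.49e-06). Of 40 general stress genes, 38 rose and 1 fell (38 and 1 adjusted over the list alone; median 3.50, camera adjusted p = 2.47e-21, and adjusted p = 0.0799 with an estimated correlation). SIP18, a phospholipid-binding hydrophilin, rose by 5.91 ± 0.30 (adjusted p = 1.08e-10) and the small heat shock protein gene HSP12 by 5.77 ± 0.62 (adjusted p = 5.13e-07). All 37 genes of the respiratory chain and ATP synthase rose (37 adjusted over the list alone; median 2.52, camera adjusted p = 5.5e-22, and 0.0428 with an estimated correlation). The external NADH dehydrogenase gene NDE2 was at 4.54 ± 0.38 (adjusted p = 2.83e-08). Of 28 glucose-repressed carbon use genes, 24 rose and 1 fell (25 and 1 adjusted over the list alone; median 3.06, camera adjusted p = 8.85e-13, and 0.0493 with an estimated correlation). Isocitrate lyase ICL1 was at 4.47 ± 0.51 (adjusted p = 1.03e-06).

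Further lists moved in the same comparison. Of 20 trehalose and glycogen genes 17 rose (19 adjusted over the list alone; median 1.73, camera adjusted p = 5.81e-07, and adjusted p = 0.196 with an estimated correlation). Of 12 TCA cycle genes 10 rose (11 adjusted over the list alone; median 1.64, camera adjusted p = 1.16e-05, and adjusted p = 0.0909 with an estimated correlation). Of 28 G1/S cell cycle genes 16 fell (18 adjusted over the list alone; median -1.09, camera adjusted p = 1.78e-07, and 0.041 with an estimated correlation). Ribonucleotide reductase RNR1 was at -3.28 ± 0.37 (adjusted p = 9.57e-07) and the G1 cyclin gene CLN1 at -2.88 ± 0.31 (adjusted p = 4.94e-07). Of 13 daughter-cell separation genes 10 fell (10 adjusted over the list alone; median -1.56, camera adjusted p = 3.48e-06, and 0.0493 with an estimated correlation). EGT2, which acts in septum degradation, was at -3.52 ± 0.32 (adjusted p = 6.53e-08). Of 51 amino acid biosynthesis genes 27 fell and 4 rose (27 and 5 adjusted over the list alone; median -0.98, camera adjusted p = 3.07e-05, and adjusted p = 0.0956 with an estimated correlation). Fatty acid beta-oxidation genes rose (8 higher and 1 lower of 16, the same 2 numbers adjusted over the list alone; median 0.50, camera adjusted p = 0.00923, and adjusted p = 0.0909 with an estimated correlation), a call that ended on the filter of dim probe sets (adjusted p = 0.13), and the peroxisomal thiolase gene POT1 rose by 3.67 ± 0.28 (adjusted p = 1.35e-08). The calls of the DNA damage response list (6 higher of 15, 7 higher and 1 lower adjusted over the list alone; median 0.72, camera adjusted p = 0.0414, and adjusted p = 0.0909 with an estimated correlation) and of the a-specific genes (3 higher of 7, 3 adjusted over the list alone; median 0.61, camera adjusted p = 0.0283, and adjusted p = 0.326 with an estimated correlation) did not hold without wild-type exponential replicate 2 (0.0765 in both lists), nor did the first hold without wild-type depletion replicate 2 (0.067) or on the dim filter (0.13). Neither held with the length trend removed (0.0529 and 0.0672), and the a-specific median was 0.959 without wild-type exponential replicate 1.

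The remaining lists were not called as lists in the wild type (counts higher and lower, with those adjusted over the list alone after them). None of the 9 subunit genes of the complex was called on the probe set used (0 adjusted over the list alone; median 0.09, camera adjusted p = 0.927), although another probe set of CDC39, the gene of Not1, was called at -0.82 (adjusted p = 0.0151). The mRNA decay factors had 1 higher and 6 lower of 29 (1 and 6; -0.33, adjusted p = 0.098), with the RNA-binding protein gene PUB1 at -1.69 ± 0.36 (adjusted p = 0.00089). Mitochondrial ribosomal proteins had 6 and 1 of 71 (0 and 0; 0.20, adjusted p = 0.353), glycolysis and fermentation 1 and 6 of 16 (1 and 6; -0.44, adjusted p = 0.0769), hexose transporters 6 and 3 of 13 (6 and 3; 0.45, adjusted p = 0.635), heat shock chaperones 10 and 1 of 24 (11 and 2; 0.65, adjusted p = 0.0596) and the proteasome 2 and 0 of 33 (1 and 0; 0.15, adjusted p = 0.353). Among the hexose transporters, HXT5 rose by 3.95 ± 0.31 (adjusted p = 1.53e-08) and HXT1, the low-affinity carrier, was at -3.05 ± 0.41 (adjusted p = 5.74e-06). The pheromone response list had 8 and 2 of 22 (9 and 2; 0.60, adjusted p = 0.0769), histones 0 and 2 of 4 (0 and 2; -0.55, adjusted p = 0.261), cell wall integrity 2 and 10 of 25 (3 and 10; -0.23, adjusted p = 0.0769), flocculation and adhesion 1 and 0 of 5 (1 and 0; 0.84, adjusted p = 0.457), the iron regulon 8 and 4 of 21 (8 and 5; 0.45, adjusted p = 0.545), alpha-specific genes 0 and 0 of 4 (0 and 0; -0.10, adjusted p = 0.927) and auxotrophic marker genes 0 and 3 of 7 (0 and 3; -0.22, adjusted p = 0.13). In all, 2205 genes changed, 1146 higher and 1059 lower, and 1464 changed without wild-type exponential replicate 1. The split turned to 1069 higher and 1206 lower after quantile normalization and 865 and 877 without wild-type exponential replicate 2.

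The exponential caf1 strain had higher transcripts of mating and respiratory genes. FIG1, a membrane protein gene induced by mating pheromone, rose by 4.80 ± 0.32 (adjusted p = 8.58e-09), and the high-affinity phosphate transporter gene PHO84 by 4.79 ± 0.44 (adjusted p = 6.88e-07). The anaerobic cell wall mannoprotein genes DAN1 and TIR1 fell by 3.96 ± 0.33 (adjusted p = 1.87e-07) and 3.23 ± 0.28 (adjusted p = 2.34e-07), and ANB1, the hypoxic form of translation factor eIF5A, fell by 3.19 ± 0.34 (adjusted p = 5.66e-06). Of 22 pheromone response genes 9 rose (10 adjusted over the list alone; median 0.83, camera adjusted p = 9.78e-08, and adjusted p = 0.102 with an estimated correlation). FIG2 was at 2.84 ± 0.51 and PRM3 at 2.54 ± 0.27. Of 37 respiratory chain genes 10 rose (19 adjusted over the list alone; median 0.80, camera adjusted p = 3.61e-09, and adjusted p = 0.279 with an estimated correlation), led by the complex III gene QCR10 at 2.47 ± 0.34 (adjusted p = 0.000196). In all 252 genes changed, 192 higher and 60 lower. The count was 40 without caf1 replicate 2, 59 without wild-type replicate 1 and 86 without wild-type replicate 2. After quantile normalization it was 142 higher and 90 lower.

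In the exponential arrays labelled caf130, DAN1 fell by 3.91 ± 0.33 (adjusted p = 9.36e-07), and that call held in each setting that tested it. DAN1 was 1 of 38 genes called, 22 higher and 16 lower. It fell by similar amounts in caf1 and not5 against the same wild-type arrays, whose own level was not told apart from a deletion effect. Of 20 trehalose and glycogen genes 3 fell (11 adjusted over the list alone; median -0.83, camera adjusted p = 4.21e-11, and adjusted p = 0.379 with an estimated correlation). The median was -0.52 without wild-type replicate 2. None of the 24 heat shock chaperone genes was called (0 adjusted over the list alone), although the list as a whole lay lower (median -0.51, camera adjusted p = 4.93e-06, and adjusted p = 0.392 with an estimated correlation). The count was 14 and 1 (lower) without replicates 1 and 2 of the arrays labelled caf130, and 12 (2 higher and 10 lower) and 8 without wild-type replicates 1 and 2. The split was 20 higher and 25 lower after quantile normalization, and 16 and 27 with a trend on coding length removed.

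The exponential ccr4 strain had the highest median of the pheromone response list among the 7 strains. Of its 22 genes 16 rose (20 adjusted over the list alone; median 2.02, camera adjusted p = 1.99e-29, and 0.000359 with an estimated correlation). FIG1 rose by 6.15 ± 0.32 (adjusted p = 1.61e-10), FIG2, a cell wall adhesin of mating cells, by 5.31 ± 0.51 (adjusted p = 8.75e-07) and PRM2 by 4.15 ± 0.38 (adjusted p = 6.5e-07). Genes specific to each mating type rose as well. Of 7 a-specific genes 5 rose (6 adjusted over the list alone; median 1.71, camera adjusted p = 2.93e-09, and 0.0279 with an estimated correlation). AGA2, the a-agglutinin binding subunit, was at 2.69 ± 0.35 (adjusted p = 4.8e-05). Of 4 alpha-specific genes 3 rose (4 adjusted over the list alone; median 2.15, camera adjusted p = 5.67e-07, and 0.0279 with an estimated correlation). SAG1, the alpha-agglutinin, was at 3.59 ± 0.46 (adjusted p = 3.78e-05). Of 13 hexose transporter genes 4 rose (4 adjusted over the list alone; median 0.62, camera adjusted p = 0.000119, and 0.0279 with an estimated correlation). That median was 0.357 without ccr4 replicate 1. Of 28 G1/S genes 3 fell (9 adjusted over the list alone; median -0.59, camera adjusted p = 3.88e-05, and 0.0309 with an estimated correlation). In all 383 genes changed, 232 higher and 151 lower. The count was 75 without ccr4 replicate 1 and 111 and 113 without wild-type replicates 1 and 2. The split was 240 higher and 99 lower with the length trend removed.

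In the exponential not2 strain all 7 a-specific genes fell (7 adjusted over the list alone; median -4.13, camera adjusted p = 3.7e-15, and 0.0164 with an estimated correlation). BAR1, the protease that degrades alpha-factor, fell by 4.40 ± 0.32 (adjusted p = 1.59e-08), the a-factor genes MFA1 and MFA2 were at -4.26 ± 0.28 and -4.19 ± 0.27 (adjusted p = 4.05e-09 for both), and the alpha-factor receptor gene STE2 was at -4.13 ± 0.28 (adjusted p = 5.49e-09). Of 22 pheromone response genes 9 fell and 1 rose (9 and 2 adjusted over the list alone; median -0.51, camera adjusted p = 0.000439, and adjusted p = 0.302 with an estimated correlation). The pheromone arrest gene FAR1 was at -3.19 ± 0.39 (adjusted p = 1.52e-05) and the MAP kinase gene FUS3 at -2.27 ± 0.43 (adjusted p = 0.00124). Of the other probe sets of FUS3, 1 was at -2.61 (adjusted p = 0.00154) and 1 at -0.34, not called. The median was -0.342 without wild-type replicate 1. SPG4, needed for survival in stationary phase, rose by 5.44 ± 0.58 (adjusted p = 3.51e-06), HSP12 by 4.72 ± 0.62 (adjusted p = 3.61e-05) and the phosphate transporter genes PHO84 and PHO89 by 4.84 ± 0.44 (adjusted p = 3.85e-07) and 4.46 ± 0.43 (adjusted p = 8.94e-07). Of 13 daughter-cell separation genes 8 rose (9 adjusted over the list alone; median 1.11, camera adjusted p = 0.00461, and adjusted p = 0.366 with an estimated correlation). DSE3 was at 1.90 ± 0.38 (adjusted p = 0.00166). Of 21 iron regulon genes 8 rose (8 adjusted over the list alone), among them the siderophore transporter gene SIT1 at 3.36 ± 0.46 (adjusted p = 6.01e-05), but the list call (median 0.52, camera adjusted p = 0.0203, and adjusted p = 0.851 with an estimated correlation) ended without not2 replicate 1 (0.125), without wild-type replicate 2 (0.054) and on the dim filter (0.0523). In all 1277 genes changed, 877 higher and 400 lower. The count was 401 without not2 replicate 2, 452 without wild-type replicate 1 and 708 without wild-type replicate 2. The split was 618 higher and 631 lower after quantile normalization, which moved the median of all genes by -0.147, and 649 and 601 with the length trend removed.

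The exponential not3 strain had higher transcripts of hexose carriers and of the phosphate carrier gene PHO84. PHO84 rose by 4.81 ± 0.44 (adjusted p = 3.86e-06), and the hexose carrier genes HXT4 and HXT6 by 3.25 ± 0.40 (adjusted p = 0.000137) and 2.62 ± 0.46 (adjusted p = 0.00572). PHO84 rose by similar amounts in caf1 and not2 against the same wild-type arrays, whose own level was not told apart from a deletion effect. Of the 13 hexose transporter genes 3 rose (5 higher and 1 lower adjusted over the list alone; median 0.66, camera adjusted p = 0.000378, and adjusted p = 0.0768 with an estimated correlation). Of 22 pheromone response genes 3 rose (3 adjusted over the list alone; median 0.57, camera adjusted p = 0.00102, and adjusted p = 0.171 with an estimated correlation). FIG1 was at 2.31 ± 0.32 (adjusted p = 0.000609), and 3 of 7 a-specific genes rose (7 adjusted over the list alone; median 0.86, camera adjusted p = 1.24e-05, and adjusted p = 0.125 with an estimated correlation). ASG7 was at 2.11 ± 0.34 (adjusted p = 0.00299). In all 173 genes changed, 132 higher and 41 lower, and 89 and 53 after quantile normalization. The count fell on leaving out any 1 array of not3 or wild type, and was 275 with the spread of the exponential arrays only.

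In the single exponential not4 array the lowest genes included DED1, an RNA helicase of translation initiation, at -5.23 ± 0.67 (adjusted p = 9.36e-05) and HEM1, which starts heme synthesis, at -4.26 ± 0.59 (adjusted p = 0.000267). Probe sets of the same gene disagreed more on this array than on the other 13 exponential arrays (median SD 0.439 over 108 genes, against 0.111 to 0.259). The decapping activator gene DHH1 fell by 3.54 ± 0.72 (adjusted p = 0.00582) and PUB1 by 3.78 ± 0.44 (adjusted p = 4.28e-05). SNZ1 and SNO1, of vitamin B6 synthesis, rose by 3.67 ± 0.39 (adjusted p = 1.74e-05) and 2.96 ± 0.35 (adjusted p = 4.28e-05), and the siderophore transporter gene ARN2 by 3.38 ± 0.38 (adjusted p = 3.1e-05). Of 37 respiratory chain genes 9 fell (9 adjusted over the list alone; median -0.38, camera adjusted p = 0.00011, and adjusted p = 0.643 with an estimated correlation). The ATP synthase gene ATP3 was at -2.70 ± 0.49 (adjusted p = 0.00229). Of 28 G1/S genes 8 rose (12 adjusted over the list alone; median 0.81, camera adjusted p = 0.000304, and adjusted p = 0.123 with an estimated correlation). In all 465 genes changed, 271 higher and 194 lower. The count was 143 (62 higher and 81 lower) and 156 (65 and 91) without wild-type replicates 1 and 2. The split was 189 higher and 238 lower after quantile normalization, which moved the median of all genes by -0.105, and 207 and 262 with the length trend removed.

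The single exponential not5 array had higher stress and glucose-repressed genes. Of 40 general stress genes 17 rose (28 adjusted over the list alone; median 1.46, camera adjusted p = 1.1e-20, and adjusted p = 0.0992 with an estimated correlation). GRE1, a hydrophilin, was at 5.12 ± 0.42 (adjusted p = 5.23e-07) and HSP12 at 5.11 ± 0.76 (adjusted p = 0.000311). Of 28 glucose-repressed genes 11 rose (15 higher and 1 lower adjusted over the list alone; median 1.30, camera adjusted p = 6.98e-10, and adjusted p = 0.0992 with an estimated correlation). The gluconeogenic enzyme gene FBP1 was at 3.97 ± 0.64 (adjusted p = 0.000593) and ADH2 at 3.89 ± 0.56 (adjusted p = 0.00028). Of 51 amino acid biosynthesis genes 9 fell (11 adjusted over the list alone; median -0.49, camera adjusted p = 6.58e-06, and adjusted p = 0.0992 with an estimated correlation). Of 16 beta-oxidation genes 3 rose (5 adjusted over the list alone; median 0.70, camera adjusted p = 4.35e-05, and adjusted p = 0.066 with an estimated correlation). ANB1 was at -3.80 ± 0.41 (adjusted p = 1.79e-05) and DAN1 at -3.58 ± 0.40 (adjusted p = 2.47e-05). Both were low in caf1 too, against the same wild-type arrays, whose own level was not told apart from a deletion effect. The labels name flocculation of this strain after glucose depletion. In exponential phase the flocculin gene FLO5 rose by 2.76 ± 0.41 (adjusted p = 0.000305), and FLO1 was at 4.19 ± 0.91 (adjusted p = 0.00951), a call not made without wild-type replicate 1 (3.98, adjusted p = 0.0696). FLO8 (0.81), FLO10 (0.59) and FLO11 (0.23) were not called, so 2 of 5 measured members rose (2 adjusted over the list alone; median 0.81, camera adjusted p = 0.00294, and adjusted p = 0.2 with an estimated correlation). In all 296 genes changed, 210 higher and 86 lower. Without wild-type replicate 1, 96 changed.

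After glucose depletion the caf1 strain, measured on 1 array, had higher transcripts of genes for cell separation and the cell wall. Of 13 daughter-cell separation genes 11 rose (12 adjusted over the list alone; median 2.20, camera adjusted p = 3.27e-11, and 0.0118 with an estimated correlation). The endoglucanase gene DSE4 was at 3.92 ± 0.48 (adjusted p = 6.73e-05) and SUN4 at 3.70 ± 0.38 (adjusted p = 5.29e-06). Of 25 cell wall integrity genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.93, camera adjusted p = 0.000184, and adjusted p = 0.681 with an estimated correlation). The wall protein gene PIR1 was at 4.03 ± 0.39 (adjusted p = 2.75e-06), the MAP kinase gene SLT2 at 2.51 ± 0.41 (adjusted p = 0.00111), and, outside that list, the exoglucanase gene EXG1 at 4.16 ± 0.33 (adjusted p = 1.77e-07). Of 7 a-specific genes 6 fell (6 adjusted over the list alone; median -1.45, camera adjusted p = 1.05e-05, and adjusted p = 0.222 with an estimated correlation). BAR1 was at -1.87 ± 0.40 (adjusted p = 0.00612). In all 757 genes changed, 454 higher and 303 lower. The count fell without either wild-type depletion replicate, and without replicate 2 more of the called genes were lower than higher. It was 211 with the spread of the depletion arrays only. The split was 265 higher and 282 lower after quantile normalization and 382 and 394 with the length trend removed.

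The depletion arrays labelled caf130 differed from wild type in 2 genes by limma, and 253 passed at an unadjusted p under 0.05. The 2 arrays of this group differed by an SD of 0.22 across genes and those of wild type by 0.3. The SEs rest on the spread pooled over all groups, so small shifts may have gone uncalled. TRP1 was higher (4.54 ± 0.41, adjusted p = 3.58e-06). The ferric and cupric reductase gene FRE7 was at -2.16 ± 0.37 (adjusted p = 0.0254), a call lost without replicate 1 (adjusted p = 0.08) or 2 (adjusted p = 1) of the arrays labelled caf130 and without wild-type depletion replicate 1 (adjusted p = 0.462) or 2 (adjusted p = 0.277), so that the count was 1 each time. No cytosolic ribosomal protein gene was called among 80, although 19 fell adjusted over the list alone and the list lay lower as a whole (median -0.63, camera adjusted p = 5.8e-39, and adjusted p = 0.18 with an estimated correlation). The filter of dim probe sets left 0 genes called, since it removed both, and quantile normalization gave 2 higher and 1 lower.

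The ccr4 strain after depletion had higher ribosome-related and mating transcripts and lower transcripts of stress and glucose-repressed genes than wild type. Of 79 ribosome biogenesis genes 54 rose (64 adjusted over the list alone; median 1.48, camera adjusted p = 5.28e-19, and adjusted p = 0.252 with an estimated correlation). SOF1 was at 2.91 ± 0.47 (adjusted p = 0.000219) and EBP2 at 2.71 ± 0.41 (adjusted p = 0.000163). Of 71 mitochondrial ribosomal protein genes 43 rose (50 adjusted over the list alone; median 1.03, camera adjusted p = 1.02e-12, and adjusted p = 0.252 with an estimated correlation). Of 28 glucose-repressed genes 21 fell (24 adjusted over the list alone; median -1.65, camera adjusted p = 1.6e-12, and adjusted p = 0.0663 with an estimated correlation). ICL1 was at -3.97 ± 0.51 (adjusted p = 2.58e-05) and the carnitine acetyltransferase gene YAT2 at -3.39 ± 0.39 (adjusted p = 1.03e-05). Of 40 stress genes 20 fell (24 adjusted over the list alone; median -1.24, camera adjusted p = 3.71e-12, and adjusted p = 0.252 with an estimated correlation). SIP18 was at -4.60 ± 0.30 (adjusted p = 1.19e-08) and the catalase gene CTT1 at -3.17 ± 0.54 (adjusted p = 0.000376). Of 22 pheromone response genes 13 rose (16 adjusted over the list alone; median 1.23, camera adjusted p = 8.22e-08, and adjusted p = 0.0545 with an estimated correlation). FIG1 was at 3.84 ± 0.32 (adjusted p = 2.35e-07). Of 28 G1/S genes 15 rose (19 higher and 1 lower adjusted over the list alone; median 0.86, camera adjusted p = 7.28e-06, and adjusted p = 0.0545 with an estimated correlation). RNR1 was at 2.21 ± 0.37 (adjusted p = 0.000321) and the cyclin gene CLB6 at 2.08 ± 0.29 (adjusted p = 7.96e-05). In all 1530 genes changed, 861 higher and 669 lower, and 779 and 512 changed without ccr4 depletion replicates 1 and 2, and 632 and 767 without wild-type depletion replicates 1 and 2. The split turned to 772 higher and 805 lower with the length trend removed and to 382 and 385 without wild-type depletion replicate 2.

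In the not2 strain after depletion all 13 daughter-cell separation genes rose (13 adjusted over the list alone; median 2.40, camera adjusted p = 2.22e-13, and 0.00576 with an estimated correlation). DSE4 was at 4.92 ± 0.39 (adjusted p = 5.51e-08) and EGT2 at 4.30 ± 0.32 (adjusted p = 1.87e-08). All 7 a-specific genes fell (7 adjusted over the list alone; median -3.72, camera adjusted p = 1.32e-11, and 0.0243 with an estimated correlation). MFA1 was at -4.71 ± 0.28 (adjusted p = 1.29e-09) and AGA2 at -3.89 ± 0.35 (adjusted p = 3.06e-07). Of 22 pheromone response genes 11 fell (14 adjusted over the list alone; median -0.88, camera adjusted p = 6.22e-06, and adjusted p = 0.0638 with an estimated correlation). Of 16 fatty acid beta-oxidation genes 8 rose (11 adjusted over the list alone; median 1.11, camera adjusted p = 9.01e-05, and 0.028 with an estimated correlation). The isomerase gene ECI1 was at 2.80 ± 0.29 (adjusted p = 1.28e-06) and the peroxisomal transporter gene PXA1 at 2.40 ± 0.31 (adjusted p = 1.52e-05). Of 80 cytosolic ribosomal protein genes 33 fell (35 adjusted over the list alone; median -0.62, camera adjusted p = 2.33e-07, and adjusted p = 0.652 with an estimated correlation). RPS28B was at -2.50 ± 0.26 (adjusted p = 1.44e-06). The median was -0.987 without not2 depletion replicate 1 and -0.263 without replicate 2. In all 1586 genes changed, 794 higher and 792 lower, and 939 and 808 changed without wild-type depletion replicates 1 and 2. This even split leaned either way with the setting, from 341 higher and 467 lower without wild-type depletion replicate 2 to 505 and 434 without wild-type depletion replicate 1. The 2 not2 depletion arrays differed by an SD of 0.80 across genes, against 0.22 to 0.57 in the groups other than not2 and not4 after depletion, while the SEs rest on the spread pooled over all groups.

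The not4 strain after depletion had higher cell separation, G1/S and ribosomal protein transcripts. Of 13 daughter-cell separation genes 11 rose (11 adjusted over the list alone; median 2.42, camera adjusted p = 5.99e-17, and 0.00209 with an estimated correlation). DSE1 was at 4.63 ± 0.59 (adjusted p = 2.74e-05) and EGT2 at 3.12 ± 0.32 (adjusted p = 2.55e-06). Of 28 G1/S genes 17 rose (17 adjusted over the list alone; median 1.01, camera adjusted p = 3.41e-12, and 0.00236 with an estimated correlation). CLN1 was at 3.34 ± 0.31 (adjusted p = 1.29e-06) and the DNA polymerase alpha gene POL1 at 2.82 ± 0.32 (adjusted p = 6.86e-06). Of 80 cytosolic ribosomal protein genes 32 rose and 1 fell (44 and 1 adjusted over the list alone; median 0.75, camera adjusted p = 4.32e-16, and adjusted p = 0.319 with an estimated correlation). RPS14B was at 1.98 ± 0.26 (adjusted p = 4.62e-05). ECM13 fell by 3.74 ± 0.34 (adjusted p = 1.29e-06) and FRE7 by 3.31 ± 0.37 (adjusted p = 6.1e-06). In all 687 genes changed, 335 higher and 352 lower. The count fell without not4 depletion replicate 1 or either wild-type depletion replicate, and rose without not4 depletion replicate 2. Without either wild-type depletion replicate more of the called genes were higher than lower. With the spread of the depletion arrays only the count was 332. The split also turned, to 360 higher and 310 lower after quantile normalization, 317 and 297 on the dim filter, 399 and 326 with the length trend removed and 189 and 167 without not4 depletion replicate 1. The 2 not4 depletion arrays differed more than those of any other group (SD 0.83 across genes), while the SEs rest on the pooled spread.

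**Figure D2:**
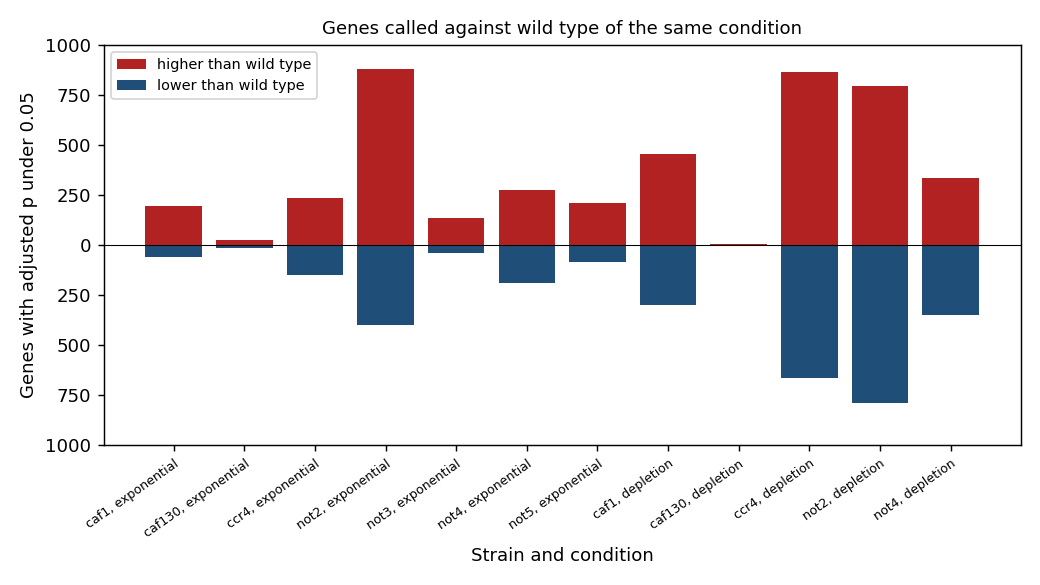
Number of genes with adjusted p under 0.05 (vertical axis) that were higher (bars above 0) or lower (bars below 0) than wild type of the same condition, for each strain and condition (horizontal axis). The counts run from 1 higher and 1 lower in the depletion arrays labelled caf130 to 877 higher in exponential not2 and 792 lower in not2 after depletion, and these are counts of single comparisons, without error bars.

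**Figure D3:**
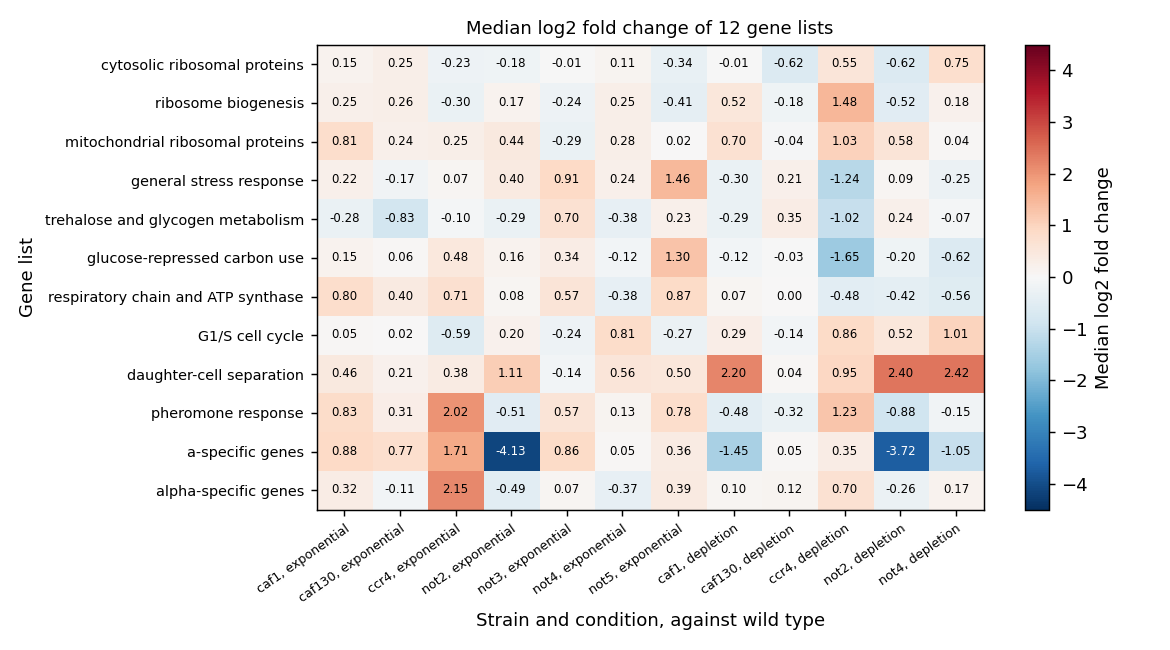
Median log2 fold change against wild type of the same condition (colour and printed value) for 12 gene lists (vertical axis) in each strain and condition (horizontal axis). Daughter-cell separation genes have medians of 2.20, 2.40 and 2.42 in caf1, not2 and not4 after depletion, and a-specific genes have medians of -4.13 and -3.72 in not2.

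Within the mutants, glucose depletion changed 1720 genes in caf1 (933 higher and 787 lower), 2836 in the arrays labelled caf130 (1312 and 1524, between conditions that also differ in TRP1), 2090 in ccr4 (1339 and 751), 2526 in not2 (1092 and 1434) and 1761 in not4 (728 and 1033). The caf1 split turned to 769 higher and 860 lower after quantile normalization and 904 and 964 with the length trend removed, and the not4 split to 911 and 899 with that trend removed. In ccr4 the split was 985 higher and 971 lower after quantile normalization, which moved the median of all genes by -0.189, and 892 and 1071 with the length trend removed. The ccr4 count was 1117 without exponential replicate 1 and 1296 and 1143 without depletion replicates 1 and 2. With the spread of the compared arrays only, the counts were 1635 in not2 and 453 (290 higher and 163 lower) in not4. Whether a mutant's response differed from that of wild type was tested as the difference of the 2 responses.

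In ccr4 that difference was called in 1095 genes, 655 higher and 440 lower. Of 28 glucose-repressed genes 21 had a lower response (24 adjusted over the list alone; median -2.44, camera adjusted p = 1.88e-14, and adjusted p = 0.0608 with an estimated correlation). The gluconeogenic gene PCK1 was at -3.72 ± 0.75 (adjusted p = 0.00277) and ICL1 at -3.58 ± 0.72 (adjusted p = 0.00277). Of 79 ribosome biogenesis genes 49 had a higher response (60 adjusted over the list alone; median 1.90, camera adjusted p = 3.02e-16, and adjusted p = 0.21 with an estimated correlation). NOP15 was at 3.46 ± 0.72 (adjusted p = 0.0033) and EBP2 at 3.32 ± 0.59 (adjusted p = 0.00128). Of 28 G1/S genes 17 had a higher response (18 adjusted over the list alone; median 1.47, camera adjusted p = 1.86e-09, and 0.0153 with an estimated correlation). CDC21 was at 2.86 ± 0.45 (adjusted p = 0.000531), and PCL1, a cyclin of the Pho85 kinase, was at 5.21 ± 0.42 (adjusted p = 3.4e-07). Of 37 respiratory chain genes 16 had a lower response (23 adjusted over the list alone; median -1.14, camera adjusted p = 1.85e-11, and adjusted p = 0.129 with an estimated correlation). NDE2 was at -3.75 ± 0.53 (adjusted p = 0.000241). The count was 516 without ccr4 exponential replicate 1, 669 and 434 without ccr4 depletion replicates 1 and 2, 521 without wild-type exponential replicate 1, and 517 and 636 without wild-type depletion replicates 1 and 2. With the length trend removed 495 were higher and 621 lower, and quantile normalization moved the median of all genes by -0.106. Removing the length trend also recentred the arrays, and the median of all genes was 0.141 before it. This turn of the split can therefore not be credited to coding length.

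The response of daughter-cell separation genes was higher than in wild type in not2, and in the arrays of caf1 and not4, whose responses rest on 1 depletion array and 1 exponential array. It was called for 3 of 13 in caf1 (8 adjusted over the list alone; median 1.13, camera adjusted p = 2.43e-07, and 0.0353 with an estimated correlation), 6 in not2 (9 adjusted over the list alone; median 1.74, camera adjusted p = 1.61e-10, and 0.0151 with an estimated correlation) and 5 in not4 (10 adjusted over the list alone; median 1.70, camera adjusted p = 6.08e-13, and 0.00728 with an estimated correlation). SUN4 was at 3.37 ± 0.49 in caf1 (adjusted p = 0.000738), 2.37 ± 0.44 in not2 (adjusted p = 0.00267) and 4.01 ± 0.49 in not4 (adjusted p = 0.000152). In caf1 the pheromone response list had a lower response in 8 of 22 genes (1 higher and 11 lower adjusted over the list alone; median -1.47, camera adjusted p = 1.96e-08, and 0.0353 with an estimated correlation). FIG1 was at -5.63 ± 0.51 (adjusted p = 3.5e-06). Against wild type, FIG1 in caf1 was at 4.80 in exponential phase and -0.84, not called, after depletion. Its difference of responses may therefore largely restate the higher start. FIG2, PRM1 and PRM2 were also called lower than in wild type after depletion. In not2 the beta-oxidation list had a higher response in 4 of 16 genes (5 adjusted over the list alone; median 0.73, camera adjusted p = 0.000341, and 0.0484 with an estimated correlation). ECI1 was at 2.57 ± 0.41 (adjusted p = 0.000991). The median was 0.351 without not2 depletion replicate 2. In not4, which rests on its single exponential array, FAS1, of fatty acid synthase, was at 5.43 ± 0.68 (adjusted p = 0.000168) and the flavohemoglobin gene YHB1 at 4.77 ± 0.67 (adjusted p = 0.000503). Other probe sets of both genes differed. The 7 further ones of FAS1 ranged from 0.98 to 4.92 and were not called, and those of YHB1 were at -0.95 and 2.13, not called, and at 4.51 (adjusted p = 0.00111). DAN1 fell by 4.47 ± 0.33 in wild type (adjusted p = 9.33e-09) and was at -0.47 ± 0.33 in the arrays labelled caf130, and this difference between conditions and strains was called (SE 0.47, adjusted p = 0.000214). DAN1 was already lower than in wild type in the exponential arrays labelled caf130, and it was not called between them after depletion. The difference of responses may therefore restate that gap in exponential phase, to which a high level in the shared wild-type arrays may contribute.

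The counts behind these differences were 134 genes in caf1 (46 higher and 88 lower), 2 in the arrays labelled caf130 (1 and 1, with 592 at an unadjusted p under 0.05), 392 in not2 (135 and 257) and 236 in not4 (101 and 135). For caf1 the count was 65 without its exponential replicate 2, 82 and 58 without wild-type exponential replicates 1 and 2, and 64 and 43 without wild-type depletion replicates 1 and 2. For the arrays labelled caf130 the genes were DAN1 and FRE7, named after their values were seen. FRE7 (-2.93 ± 0.52, adjusted p = 0.0435) was lost after quantile normalization (adjusted p = 0.0556), with a replicate block (adjusted p = 0.0785), without replicate 2 of the exponential arrays labelled caf130 (adjusted p = 0.431), without wild-type exponential replicate 1 (adjusted p = 0.0918), without replicates 1 (adjusted p = 0.065) and 2 (adjusted p = 0.324) of the depletion arrays labelled caf130, and without wild-type depletion replicates 1 (adjusted p = 0.413) and 2 (adjusted p = 0.122). The count for those arrays was 8 and 4 without wild-type exponential replicates 1 and 2, 1 without each of the 4 depletion arrays, 1 (higher) after quantile normalization, 1 on the dim filter and 4 with the length trend removed. For not2 it was 189 without its exponential replicate 2, 780 without its depletion replicate 2, 250 and 151 without wild-type exponential replicates 1 and 2, and 117 and 173 without wild-type depletion replicates 1 and 2. The not2 split was 194 higher and 185 lower after quantile normalization, which moved the median of all genes by 0.155, and 184 and 183 with the length trend removed. For not4 it was 81 without either wild-type exponential replicate (51 higher and 30 lower without replicate 2), 420 and 399 without its depletion replicates 1 and 2, and 55 (37 and 18) and 69 (35 and 34) without wild-type depletion replicates 1 and 2. The not4 split was 125 higher and 88 lower after quantile normalization, which moved the median of all genes by 0.146, and 156 and 88 with the length trend removed.

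The series title asks for specific roles of the subunits, so the exponential not2, not3, not4 and not5 strains were compared with caf1 and ccr4. Mating genes were lower on the NOT side than in caf1 and ccr4. Of 22 pheromone response genes 17 were lower (18 adjusted over the list alone; median -1.28, camera adjusted p = 8.07e-21, and 0.00176 with an estimated correlation). FIG1 was at -4.21 ± 0.21 (adjusted p = 8.34e-11), FIG2 at -3.43 ± 0.34 (adjusted p = 6.41e-07) and PRM3 at -2.66 ± 0.18 (adjusted p = 4.17e-09). Against wild type FIG1 was at 2.313 in not3, 2.655 in not5, 0.567 in not4 and -0.486 in not2. It was at 4.796 in caf1 and 6.153 in ccr4, so the difference in FIG1 comes largely from rises in those 2 strains. Of 7 a-specific genes 6 were lower (6 adjusted over the list alone; median -1.82, camera adjusted p = 2.31e-11, and 0.0262 with an estimated correlation). Against wild type the a-specific medians were -4.13 in not2 but 0.86 in not3, 0.05 in not4 and 0.36 in not5. ASG7 was at -2.92 ± 0.23 (adjusted p = 3.66e-08). All 4 alpha-specific genes were lower too (4 adjusted over the list alone; median -1.29, camera adjusted p = 3.26e-05, and adjusted p = 0.0989 with an estimated correlation). SAG1 was at -1.90 ± 0.30 (adjusted p = 0.000233). TRP1 was at -5.12 ± 0.27 (adjusted p = 1.05e-10), and ADE1, of adenine synthesis, was higher by 2.11 ± 0.25 (adjusted p = 9.01e-06), so a marker difference coincides with this comparison and limits it. Of 40 stress genes 16 were higher on the NOT side (16 adjusted over the list alone; median 0.59, camera adjusted p = 0.0003, and adjusted p = 0.629 with an estimated correlation). GRE1 was at 1.93 ± 0.23 (adjusted p = 6.91e-06). Of 37 respiratory chain genes 13 were lower (15 adjusted over the list alone; median -0.46, camera adjusted p = 1.52e-07, and adjusted p = 0.259 with an estimated correlation). COX5A was at -1.02 ± 0.17 (adjusted p = 0.000416). In all 1141 genes differed, 711 higher and 430 lower, and 313 of them by at least 2-fold. Of the 15 ways to set 4 of these 6 strains against the other 2, 5 called as many genes, this one included, and the highest called 1331. The count was 649 without caf1 replicate 1, 741 without ccr4 replicate 2 and 596 without the not2 strain. The split was 499 higher and 498 lower after quantile normalization and 492 and 559 with the length trend removed.

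The profile of a strain against wild type was compared across genes between the 2 conditions, whose wild-type arrays differ. Genes are not independent replicates, so these values describe the profiles without a test. Pearson's r was 0.518 for not2 (covariance 0.391), 0.302 for not4 (0.171), 0.301 for caf1 (0.16), -0.009 for ccr4 (-0.005) and -0.045 for the arrays labelled caf130 (-0.008), which may not be 1 strain in both conditions. It was 0.098 in not4 without depletion replicate 1 and 0.181 in caf1 without exponential replicate 2. For ccr4 it was 0.067 without ccr4 or wild-type exponential replicate 1, -0.072 without ccr4 exponential replicate 2 and -0.081 without wild-type exponential replicate 2. For the arrays labelled caf130 it was -0.13 and 0.048 without wild-type exponential replicates 1 and 2, and 0.061 and -0.152 without wild-type depletion replicates 1 and 2. Within a condition the strains share the wild-type arrays, which alone gave a simulated r of 0.406 for not2 and not5 in exponential phase, where 0.544 was observed (covariance 0.334, simulated 0.066). In the other 5 pairs of not2, not3, not4 and not5 r was below its simulated value: 0.349 for not2 and not3 (simulated 0.493), 0.377 for not2 and not4 (0.401), 0.381 for not3 and not4 (0.408), 0.295 for not3 and not5 (0.405) and 0.209 for not4 and not5 (0.331). The covariance was above the simulated one in all 6. For caf1 and ccr4 r was 0.494 (simulated 0.499, covariance 0.201, simulated 0.066). Among all pairs r was above its simulated value in 5 of 21 in exponential phase and 3 of 10 after depletion, and the covariance in 18 and 7. After depletion, not2 and not4 had r = 0.53 (simulated 0.502, covariance 0.344, simulated 0.067), caf1 and ccr4 had r = 0.443 (simulated 0.411, covariance 0.337, simulated 0.067), and ccr4 and the arrays labelled caf130 had r = -0.288 (simulated 0.501, covariance -0.088, simulated 0.067). The 2 wild-type arrays of a condition were not split, since each side would keep 1, so part of any excess may come from the shared arrays.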

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

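The tests of explanations here, the tests with a coding length trend removed and the splits of whole strains were chosen after the results were seen, while the comparisons and the splits of single arrays were fixed beforehand. The response to glucose depletion differed from that of wild type, by a test of the difference itself, in 134 genes in caf1, 2 in the arrays labelled caf130, 1095 in ccr4, 392 in not2 and 236 in not4. Outside the genes tested, 1079 of 2771 probe sets without a single named gene were called in at least 1 comparison of a strain with wild type, and they were not analysed further here.

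In the single not4 exponential array 194 genes were lower than in wild type. With a coding length trend removed, 191 of them were still called lower. That setting also recentred the arrays, and the median of all genes was 0.166 before it, which by itself moves genes lower. The number of genes kept therefore decides nothing about length. The slope per doubling of length was 0.051 in this array and 0.149 and 0.085 in the wild-type arrays. These slopes are small beside the falls, since 193 of the 194 were at least 2-fold. Array or RNA quality remains open and fits what was seen: this array ranked 1 of 14 exponential arrays in disagreement between probe sets of the same gene, with a median SD of 0.439 against 0.111 to 0.259 elsewhere. Loss of NOT4 is open too, because the genes' median against wild type was -0.75 in not4 depletion replicate 1, below the range of random sets of like expression (-0.17 to 0.1), but -0.1 in replicate 2, inside its range (-0.18 to 0.01). With 1 array, quality and deletion cannot be told apart, so these genes may reflect either.

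In not2 the a-specific genes were low in both conditions, and a swap with another strain of the series is argued against, since CDC36 was at most 3.81 in the not2 arrays and at least 6.97 in all others. In exponential phase an effect shared by the loss of any NOT gene is argued against as well, since the a-specific medians were 0.865 in not3, 0.046 in not4 and 0.361 in not5. After depletion it stays open: the median went the other way in not4, at -1.05 (4 of 7 called lower, camera adjusted p = 0.000108, and adjusted p = 0.296 with an estimated correlation), but caf1 was at -1.45 too (adjusted p = 1.05e-05, and adjusted p = 0.222 with an estimated correlation), ccr4 was at 0.35 (1 of 7 called lower, adjusted p = 0.882), and not3 and not5 were not analysed here in that condition. A candidate explanation is an a/alpha-like state of the strain: 7 further genes that are repressed in a/alpha cells had medians of -2.49 in exponential phase (6 called lower, random sets -0.45 to 0.84) and -0.95 after depletion (4 called lower, random sets -0.72 to 0.83). It stays open, because that gene list was written after its members had been seen, and an effect of losing Not2 itself was not tested apart from it.

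In ccr4 the glucose-repressed and ribosome biogenesis lists responded less to glucose depletion than in wild type at the preset correlation of camera (adjusted p = 1.88e-14 and 3.02e-16), but neither call held with an estimated correlation (adjusted p = 0.0608 and 0.21), and 2090 genes changed there against 2205 in wild type. Removing the coding length trend kept 88.3% of the ribosome biogenesis difference and 108.4% of the glucose-repressed one. The slope per doubling of length fell on depletion in ccr4 (0.05 and 0.041 to -0.162 and -0.184). It fell in wild type as well (0.149 and 0.085 to -0.078 and -0.09). The trend thus largely cancels from the difference, so its removal could hardly shrink these medians and decides nothing. With any 1 array left out the glucose-repressed median was -2.16 or further from 0, which argues against 1 aberrant array as the whole cause. A share of cells that had not yet responded is argued against too: a share of 94.6%, estimated from the glucose-repressed median of 0.48, predicts a ribosomal protein median of -0.06 (quartiles -0.07 to -0.05), while -1.15 was observed. That estimate assumes a wild-type response in the cells that responded. An effect of losing Ccr4 on the response is a hypothesis that may be pursued, found and tested on the same data. A difference in strain background, which the TRP1 marker may or may not reflect, was not tested apart from it. The depletion arrays labelled caf130 had high TRP1 too and differed from wild type in 2 genes, so high TRP1 alone did not bring such a profile there. That count rests on the spread pooled over all groups, which was wide for these arrays, so smaller shifts may have gone uncalled.

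For the comparison of NOT with CCR4-CAF1 deletions, whole strains were regrouped, since arrays of 1 strain cannot be exchanged freely. The 6 strains make 15 splits of 4 against 2, too few for a share under 0.05. The real split called 1141 genes, 5 splits called as many, the real one included, and the highest other called 1331. With single arrays regrouped instead, the real grouping called 44 genes and 2 of 100 splits drawn from 210 called as many, the real one included. The other of these called 163, several times the real count, and the remaining 98 called at most 13. Such a count can point to a structure of the samples other than this grouping, which was not tested further.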

How the results depend on the processing

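The removal of a coding length trend, the NOT side without not2 or not4 and the fit without the not4 exponential and caf1 depletion arrays were added after the data were seen; the other alternatives were planned. Pseudocounts were not applicable, as the table is already on a log scale. Below the threshold, the number of arrays and the signal of dim probe sets over background limit what can be called. Leaving out an array or taking the spread from fewer arrays lowers the number of samples by construction, and otherwise the cause of each shift was not tested. Removing the length trend also recentred each array, so its shifts are not those of coding length alone.

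Leaving out 1 array at a time gave counts of changed genes in exponential phase of 40 to 325 in caf1, 1 to 14 in the arrays labelled caf130, 75 to 273 in ccr4, 401 to 1156 in not2, 15 to 111 in not3, 143 to 156 in not4 and 96 to 209 in not5. After depletion they were 107 to 407 in caf1, 1 throughout in the arrays labelled caf130, 512 to 779 in ccr4, 808 to 1604 in not2 and 205 to 1301 in not4. For the response itself they were 1464 to 1742 in wild type and 1117 to 1790 in ccr4. Differences of responses ranged over 43 to 94 in caf1, 1 to 8 in the arrays labelled caf130, 434 to 970 in ccr4, 117 to 780 in not2 and 55 to 420 in not4. The NOT against CCR4-CAF1 count was 649 to 1155. The correlation between conditions was 0.181 to 0.348 in caf1, -0.152 to 0.061 in the arrays labelled caf130, -0.081 to 0.067 in ccr4, 0.416 to 0.545 in not2 and 0.098 to 0.382 in not4.

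With the spread of the arrays of that condition only, counts were 275 in not3 in exponential phase, and 211 in caf1 and 332 in not4 after depletion. With the spread of the strain's own arrays only, they were 1635 and 453 for the responses of not2 and not4. For the arrays labelled caf130 the dim filter left 0 genes after depletion, and for their difference of responses quantile normalization and the dim filter gave 1 gene each and the removed length trend 4. The NOT against CCR4-CAF1 count was 313 at a change of at least 2-fold, 596 without not2 (558 of them in the full comparison) and 1095 without not4 (848 of them). With genes called in neither condition left out, the correlation was 0.582 in not2 and 0.086 in the arrays labelled caf130.

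With the replicate number as a block, the count in the exponential arrays labelled caf130 was 23 and their difference of responses 1. The block moved no other count by over 1.5 times, ended 0 of 196 list calls and 53 of 1456 calls of named genes. Replicate numbers did not pair the samples: over 55 pairs of groups the correlation of deviations ran from -0.55 to 0.47, with 14 over 0.1 and 20 under -0.1.

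The 196 list calls were tested once per array left out, 836 tests in all. Of these tests, 784 kept the call, 51 lost it and 1 reversed it. The reversed median was that of cytosolic ribosomal proteins in the not2 difference of responses. It went from -0.32 (camera adjusted p = 0.0187) to 0.065 without not2 depletion replicate 2. Its lowest value was -0.748, without replicate 1. Calls were lost in 16 of 193 lists on the dim filter, 11 of 196 with the length trend removed and 10 of 196 after quantile normalization. With members on _s_at or _x_at sets left out, 0 of 196 were lost. Members on the other shared kinds of probe set stayed in, so a part played by these was not tested. Named gene calls were tested once per array left out, and 1366 of these 6190 tests lost the call. Of the 1456 calls, 533 were lost in at least 1 of them. Calls lost were 1 of 1304 on the dim filter, 18 of 1456 without the eBayes trend, 78 with the length trend removed and 82 after quantile normalization. With the spread of the condition's or the strain's arrays only, 134 of 1263 were lost. In the fit without the not4 exponential and caf1 depletion arrays, 2 of 1019 were lost.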

Other observations

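The 3 gene groups here were chosen after the data were seen and tested with camera in 12 comparisons each, 36 tests in all, with p-values adjusted over them. The exponential comparisons share the same wild-type arrays, so a shift common to several strains may come partly from those arrays. How well the labelling captures transfer RNA and small nucleolar RNA was not tested. Transfer RNA genes (91 measured) were higher in exponential ccr4, where 39 were called (median 1.04, adjusted p = 1.73e-32, and 0.0446 with an estimated correlation). They were higher too in caf1 (36 called, median 0.77, adjusted p = 2.62e-16, and adjusted p = 0.181 with an estimated correlation), in the arrays labelled caf130 (14 called, median 0.86, adjusted p = 8.91e-23, and adjusted p = 0.0907 with an estimated correlation) and in not3 (13 called, median 0.38, adjusted p = 1.77e-06, and adjusted p = 0.422 with an estimated correlation). In not2 30 were lower (median -0.72, adjusted p = 3.47e-12, and adjusted p = 0.225 with an estimated correlation). The medians were 0.29 in exponential not4 and -0.11 in exponential not5. After depletion 12 were lower and 1 higher in caf1 (median -0.65, adjusted p = 8.66e-07, and adjusted p = 0.418 with an estimated correlation). In the depletion arrays labelled caf130 the group lay higher with 0 genes called (median 0.43, adjusted p = 8.32e-15, and adjusted p = 0.182 with an estimated correlation).

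Small nucleolar RNA genes (57 measured), whose products guide modification of ribosomal RNA, were higher in exponential ccr4 (19 called, median 1.0, adjusted p = 2.14e-20, and 0.0374 with an estimated correlation) and in not5 (13 called, median 0.93, adjusted p = 1.34e-16, and 0.0386). They were also higher in not4 (15 higher and 1 lower, median 0.72, adjusted p = 5.92e-07, and adjusted p = 0.182 with an estimated correlation), in caf1 (8 called, median 0.41, adjusted p = 3.28e-05, and adjusted p = 0.232 with an estimated correlation) and, with 0 genes called, in the arrays labelled caf130 (median 0.43, adjusted p = 0.00133, and adjusted p = 0.404 with an estimated correlation). In ccr4 after depletion 16 were lower and 1 higher (median -0.49, adjusted p = 3.28e-05, and adjusted p = 0.232 with an estimated correlation). After depletion 17 were higher and 8 lower in not2 (median 0.24, adjusted p = 0.0415, and adjusted p = 0.591 with an estimated correlation), and 10 higher and 4 lower in not4 (median 0.32, adjusted p = 0.0174, and adjusted p = 0.54 with an estimated correlation). Phosphate regulon genes (14 measured) were higher in exponential not3 (8 called, median 1.38, adjusted p = 5.64e-13, and 0.0374 with an estimated correlation), caf1 (6 called, median 0.80, adjusted p = 2.73e-09, and 0.0386) and not5 (6 called, median 0.84, adjusted p = 5.01e-08, and 0.0446). In not2 10 were called higher (median 1.34, adjusted p = 1.35e-06, and adjusted p = 0.0684 with an estimated correlation), and in ccr4 1 (median 0.41, adjusted p = 0.00175, and adjusted p = 0.225 with an estimated correlation). The median was above 0 in exponential not4 (0.6) and in the exponential arrays labelled caf130 (0.34) too. After depletion the medians lay between -0.29 and 0.18. Low values in the shared wild-type exponential arrays would raise every strain alike and were not told apart from effects of the deletions.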
